A study of Arabidopsis thaliana with 4 samples.

How the data were processed

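RNA-seq was done on whole seeds of Arabidopsis thaliana, ecotype Columbia, with 2 biological replicates of the wild type and 2 of the ddcc mutant. Per the labels' protocols, frozen seeds were ground and total RNA was treated with DNase. About 25 ng of it was amplified with a NuGEN Ovation kit, and double-stranded cDNA went into Illumina libraries made with a TruSeq DNA kit, to which the sequencing facility added PhiX DNA. Per the submitters' processing notes, Bowtie 0.12.7, edgeR 3.10.5 and the TAIR10 genome build were used. The mapping and counting settings are not given in the sources used here, and no label states that counting used the strand, so reads of overlapping genes on either strand could not be told apart.

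The deposited values are a signal, normalised read counts for 27416 protein-coding genes, which were not whole numbers and not divided by gene length. Per the labels edgeR was used, and within each genotype the values followed that package's equalisation of library sizes. Inverting this step gave whole reads, within a tolerance of 0.01, for 100% of the value pairs of genes with reads in each genotype, at a dispersion of 0.0327. The inferred reads totalled 1122934 and 1166635 in ddcc replicates 1 and 2 and 3416071 and 1292023 in wild-type replicates 1 and 2. The corresponding normalisation factors were 1.17, 1.10, 0.855 and 0.910, and the deposited totals were 1325381, 1410907, 1815256 and 1705082. Because the values did not lie on even steps, the count tests planned for such reads were not run. The reads served for depths, for counting intervals at the 95% level, for floors and for additional analyses with voom in limma.

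The second wild-type library has a source name that says ddcc, while its title, description and genotype say wild type. It was kept as wild type and left out once as an alternative. Per the file headers both wild-type tables belong to replicate 2, but their values differ.

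The comparison, fixed before the data were examined, used limma 3.58.1 in R 4.3.3. Log2 values were taken after adding a pseudocount of 1 unit, where a unit was 1.56, the mean column total divided by 1e6. Genes with a mean of at least 1 unit over the 4 libraries were tested with a moderated fit of genotype and a variance trend on expression, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes refer to log2(value + pseudocount), which understates changes of low genes. For a gene without reads in a genotype, the fold is the ratio of the other genotype to a floor of 3 reads over the group. It leaves out the counting error of the other genotype and is not a confidence limit. For 1 to 3 reads the ratio of reads, corrected for depth, is given with an exact binomial interval. Intervals cover counting error only, and floors only that of the genotype without reads.

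The genes named were set by rule. They were the 4 targeted genes, the 6 largest changes in each direction among called genes whose higher group mean was at least 5 units and whose ddcc libraries both lay on the same side of both wild-type libraries, and in each gene list the member with the highest mean and, of the others, the one with the smallest p. Other genes appear as examples of their list or were chosen after their values were seen, which is then stated. The 18 lists covered the targeted methyltransferases, other DNA methylation and silencing genes, imprinted or methylation-silenced loci, seed storage proteins, oil body and oil synthesis genes, late embryogenesis abundant (LEA) proteins, heat shock proteins and factors, maturation regulators with abscisic acid genes, photosynthesis and chlorophyll genes, seed coat genes, germination genes, cell cycle genes, defence genes, silique wall and flower markers, endosperm markers, reference genes, and the genes of the chloroplast and of the mitochondrial genome. The 14 lists with at least 5 tested genes were tested with camera in limma at a preset correlation of 0.01, again with an estimated correlation, and with fry, each with Benjamini-Hochberg adjustment.

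Symbols, positions and products came from the TAIR10.1 reference annotation, which keeps the nuclear chromosome sequences of TAIR10. A row of its gene table was found for 26719 of the 27416 loci. Neither the tables nor this annotation mark transposable element genes as a class, so the comparison planned for them was not made. Near-identical copies of at least 95% identity over at least 100 bases were searched for with BLAST+ 2.17.0 among the transcripts and the genome. Of 42 named genes, 4 had such a copy and 8 overlapped another locus, and these are named as uncertain. After the data were seen, Fisher's exact tests on annotated processes and protein domains were added.

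The alternatives were other pseudocounts (0.5 and 5 units), no filter or a filter at 5 units, TMM factors or quantile normalisation on top, libraries scaled to equal totals of nuclear genes, limma without a trend or with robust moderation, a replicate block, each library left out in turn, an adjusted p under 0.01 and a minimum fold of 2. Voom on the inferred reads, with effective library sizes or with plain totals, and reads thinned to equal depth were added later. The test was checked on simulated data, in which all genes of both genotypes had the same dispersion. Genes that vary more than others of their level were therefore not simulated, and the shares of false calls do not cover them. At the dispersion of 0.0327, over 15630 genes, 25.8% of 2-fold, 69.7% of 4-fold and 92.4% of 8-fold changes were recovered, with 4 false calls among 128. At a dispersion of 0.131, over 15646 genes, these shares were 0%, 4.55% and 42.9%, with 1 false call among 31.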

Results

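Whole seeds holding embryos at the post-mature green stage, a late stage of seed development, were compared between wild-type Arabidopsis thaliana and the ddcc mutant. The mutant is named for the DNA methyltransferase genes DRM1, DRM2, CMT2 and CMT3, whose products methylate cytosines mostly outside CG sites. The comparison asks which transcripts of late seeds differ when these enzymes are lost. Each genotype had 2 libraries, with 1122934 and 1166635 reads on protein-coding genes in ddcc replicates 1 and 2, and 3416071 and 1292023 in wild-type replicates 1 and 2. Across genes, which are not independent replicates, log2 values correlated with a Pearson coefficient of 0.952 between the ddcc libraries, 0.947 between the wild-type libraries and 0.907 to 0.918 between genotypes. Values are deposited normalised read counts, as mean ± SD over the 2 libraries of a genotype, and the median SE of a log2 fold change was 0.37.

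DRM2, the main methyltransferase of RNA-directed DNA methylation, had normalised read counts of 4.85 and 8.33 in the ddcc libraries and 39.3 and 39.6 in the wild-type libraries. It was lower in ddcc, with a log2 fold change of -2.36 (SE 0.39, limma adjusted p = 0.00347), from 11 reads against 104. DRM1 had 0 reads in all 4 libraries. CMT3 stood at 1.2 and 1.23 in ddcc and at 4.65 and 0.177 in wild type, a difference that did not pass the test (adjusted p = 0.891). Of these genes DRM2 was also the 1 lower when adjusted over the list alone. CMT2, with 2 reads in ddcc and 1 in wild type, lay below the level tested, so that no difference in CMT2 was detectable at this depth. In TAIR10.1 coordinates DRM2 spans 4715105 to 4718704 and DRM1 4991347 to 4994924 on chromosome 5. CMT2 spans 10414428 to 10421265 on chromosome 4, and CMT3 26248118 to 26253687 on chromosome 1. The wild-type replicate whose source name says ddcc, replicate 2, had the wild-type level of DRM2 and 2.52 for SDC, against 1644 and 1897 in the ddcc libraries. The call of DRM2 was lost without ddcc replicate 1 (adjusted p = 0.248), ddcc replicate 2 (0.311), wild-type replicate 1 (0.0597) or wild-type replicate 2 (0.0667), and in limma without a trend (0.0734), with a log2 fold change between -2.67 and -2.04 in all of these.

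The largest rise in ddcc was that of SDC (AT2G17690), an F-box gene known to be silenced by non-CG methylation of repeats in its promoter, from 1.7 ± 1.16 in wild type to 1771 ± 179 in ddcc. Its log2 fold change was 9.13 (SE 0.29, adjusted p = 1.32e-10), from 4 reads in wild type and 2962 in ddcc. PUM11, a Pumilio-type RNA-binding protein gene, and the uncharacterized genes AT3G29639 and AT3G29080 had no read in wild type. Against the floor of 3 reads they were 57.8-fold, 149-fold and 45.7-fold higher in ddcc. The uncharacterized gene AT3G01345 rose from 2.56 ± 1.72 to 235 ± 3.17, and the expansin gene EXPA2 from 0.586 ± 0.761 to 47.7 ± 10.6, a read ratio of 63.1 with an interval of 16.9 to 530. The largest falls were in small heat shock protein genes and in the DNA demethylase gene DML1 (ROS1), which dropped from 168 ± 8.09 to 8.39 ± 3.29 with a log2 fold change of -4.13 (SE 0.32, adjusted p = 6.54e-06). SDC lies on chromosome 2 at 7682162 to 7684083, and AT3G29639 on chromosome 3 at 11478633 to 11480033. AT3G01345 lies on chromosome 3 at 129138 to 130749, PUM11 on chromosome 4 at 5631298 to 5633779, and AT3G29080 on chromosome 3 at 11069352 to 11071376. EXPA2 lies on chromosome 5 at 1568694 to 1569915 and DML1 on chromosome 2 at 15307907 to 15314807. SDC and EXPA2 overlap AT2G17695 and AT5G05300, and AT3G29639 has a copy of 95.6% identity elsewhere, so that their reads are uncertain in origin.

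**Figure D1:**
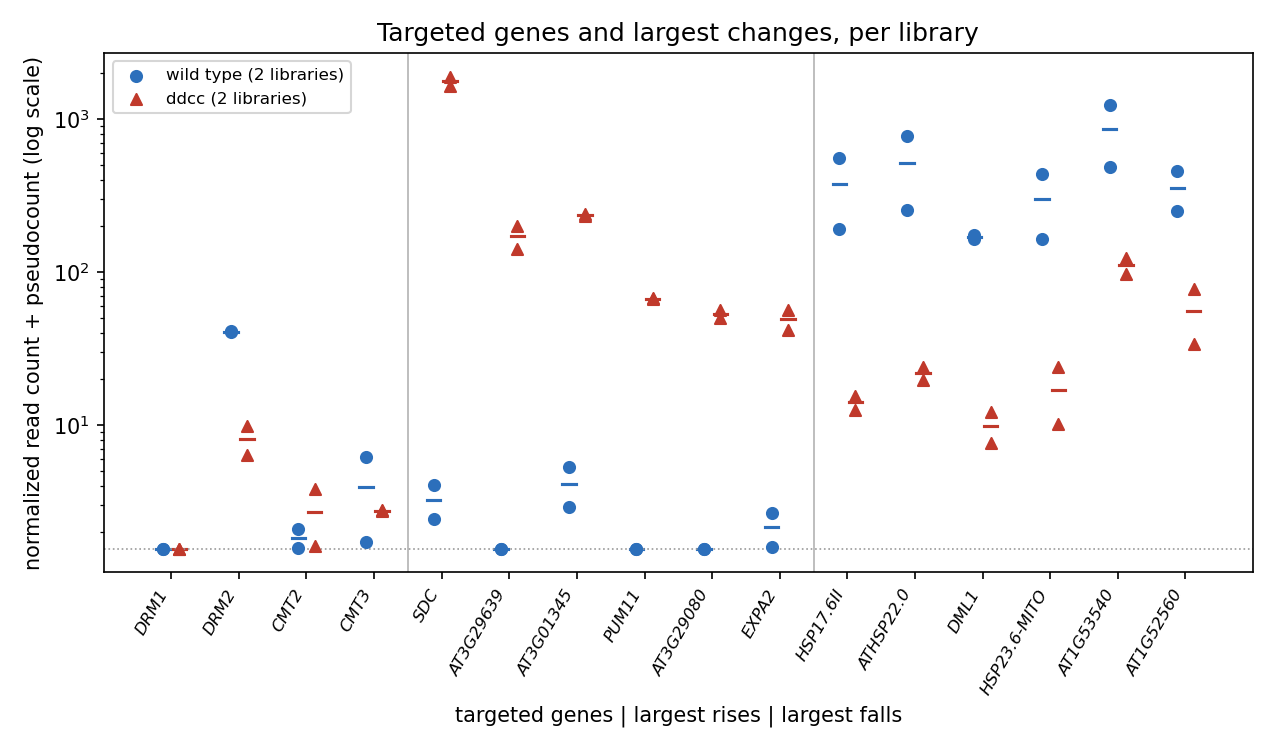
Normalised read counts plus the pseudocount (log scale) of the 4 targeted genes, the 6 largest rises and the 6 largest falls, with 1 point per library and a bar at the mean of the 2 libraries of a genotype; the dotted line marks a count of 0. SDC stands at 1644 and 1897 in ddcc, and DML1 at 6.06 and 10.7 in ddcc against 174 and 162 in wild type.

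Of 15780 genes tested, 1023 (6.48%) were called, 478 higher and 545 lower in ddcc. At least a 2-fold change was seen in 427 of the higher and 387 of the lower genes, and at least an 8-fold change in 49 and 4. With 3 reads or fewer in the wild-type libraries together, 62 genes were called higher, while 11 were called lower with 3 reads or fewer in ddcc. The split of higher against lower calls depended on scaling: 46.7% of calls were higher with the deposited normalisation and 57.2% after quantile normalisation. With libraries scaled to equal nuclear totals it was 86.9% (1349 of 1553), and this scaling shifted the median of all genes from 0.02 to 0.37 on the log2 scale. Plain library totals, an analysis chosen after the data were seen, gave 87.8% and a median of 0.40. Every one of the 1023 genes that was tested under an alternative kept its sign in it. That was fixed in advance in limma without a trend, with robust moderation, with the replicate block and with the other filters, where fold changes stay the same. Far fewer genes were called with any 1 library left out, and fewest without a ddcc library. The lone ddcc library is then assumed to vary like the wild-type libraries, so the variance came from the wild-type pair alone. That pair varied more, with a median absolute log2 difference of 0.403 against 0.329 in the ddcc pair. How far this lowered the count was not tested. Limma without a trend called 33 genes.

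**Figure D2:**
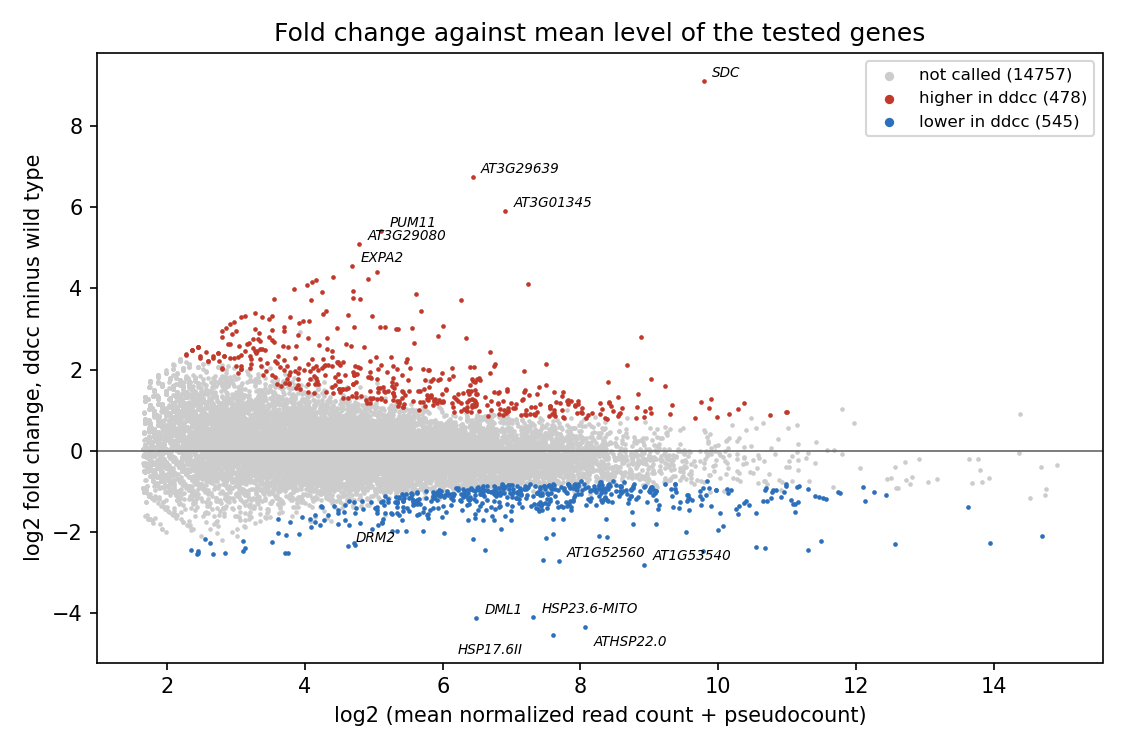
Log2 fold change of ddcc over wild type against the log2 of the mean normalised read count over the 4 libraries plus the pseudocount. Each tested gene is 1 point, with the 478 genes called higher and the 545 called lower in ddcc in colour. SDC lies at 9.13, and HSP17.6II, ATHSP22.0, DML1 and HSP23.6-MITO lie between -4.55 and -4.10.

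Among DNA methylation and silencing genes 2 rose and 2 fell, or 5 and 1 with equal nuclear totals. DML1, which encodes the glycosylase that excises methylated cytosines, fell, as did the histone demethylase gene IBM1 (68.0 ± 8.03 to 28.1 ± 3.56). DME, a DML1 relative active in the central cell of the female gametophyte, rose from 16.2 ± 1.3 to 50.8 ± 3.23 (log2 fold change 1.56, adjusted p = 0.0101), and IDN2, a component of RNA-directed methylation, rose from 44.0 ± 21.7 to 117 ± 10.3. The other 18 of the 22 tested members did not pass, among them the CG methyltransferase gene MET1 (10.2 ± 0.955 in ddcc against 2.01 ± 0.793, adjusted p = 0.0703), AGO4 (0.0772) and RDR2 (0.0636). When adjusted over the list alone, 5 members were higher and 2 lower, and the list as a whole was not called (median log2 fold change 0.54, camera adjusted p = 0.098), except in limma without a trend (0.0334). Without ddcc replicate 2 none of the 22 was called, and DML1 had an adjusted p of 0.0968, while 4 were higher and 2 lower at an unadjusted p under 0.05. IBM1 was not called without wild-type replicate 1 (adjusted p = 0.12) or 2 (0.0834) or with equal nuclear totals (0.0773), nor IDN2 without wild-type replicate 2 (0.1). DME lost its call without any 1 of the 4 libraries (adjusted p = 0.303 and 0.393 without ddcc replicates 1 and 2, 0.0617 and 0.0549 without wild-type replicates 1 and 2).

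Of imprinted genes and loci known to be silenced by methylation, 8 were tested and SDC alone was called. Through SDC the list's reads were 0.128% and 0.138% of all reads in the ddcc libraries and 0.00319% and 0.00232% in wild type. QQS, a gene whose activity varies with the methylation of nearby repeats, stood at 9.55 ± 3.0 in ddcc and 1.2 ± 1.56 in wild type (adjusted p = 0.0564), and passed with equal nuclear totals (0.0157), with TMM factors (0.0367), with robust moderation (0.0362) and with a pseudocount of 5 units (0.0427). FIS2, a Polycomb gene of the central cell and endosperm that overlaps AT2G35680 and is uncertain in origin, was at 3.59 ± 1.51 and 11.7 ± 1.89 (adjusted p = 0.125; 0.0499 after quantile normalisation), and FWA and MEA had 5 and 3 reads in ddcc. There were 2 higher and 1 lower adjusted over the list alone. The list had a median log2 fold change of 0.38 and a mean of 1.43, the latter raised by SDC at 9.13. It was not tested without SDC, so its call may rest on that gene alone. The camera adjusted p was 0.0453, which became an adjusted p = 0.325 with an estimated correlation and was 0.0402 with fry. This call was also lost after quantile normalisation (median 0.09, adjusted p = 0.14), with equal nuclear totals (0.116), in limma without a trend (0.0799), without a filter (0.149) and without any 1 of the 4 libraries (0.084, 0.0663 without ddcc replicates 1 and 2, 0.072 and 0.141 without wild-type replicates 1 and 2).

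Heat shock genes were lower in ddcc, with 12 of the 15 tested members called lower and none higher. HSP17.6II fell from 374 ± 257 to 12.5 ± 2.17 (log2 fold change -4.55, adjusted p = 1.60e-05), ATHSP22.0 from 513 ± 368 to 20.3 ± 2.87, and HSP23.6-MITO, a mitochondrial member, from 300.3 ± 193 to 15.6 ± 9.81. The most abundant member, HSP17.6A, fell from 26139 ± 8574 to 5316 ± 1259, and the small heat shock protein genes AT1G53540 and AT1G52560 had log2 fold changes of -2.81 and -2.72. HSP101, a disaggregating chaperone, HSP90.1, and HSFA9, the heat shock factor of maturing seeds, fell as well, with log2 fold changes of -1.56, -2.22 and -0.95, while HSFA2 did not pass (adjusted p = 0.121). Together the list held 0.718% and 0.842% of reads in the ddcc libraries and 2.70% and 2.79% in wild type. Adjusted over the list alone, 14 members were lower, and the list median was -1.57 (camera adjusted p = 1.03e-18; adjusted p = 0.27 with an estimated correlation and 0.0911 with fry). The members lay close to each other in part: on chromosome 5 HSP17.6II spans 3882231 to 3883111 and HSP17.6A 3883957 to 3884838. ATHSP22.0 lies on chromosome 4 at 6370338 to 6371372, HSP23.6-MITO on chromosome 4 at 12916926 to 12918110, AT1G53540 on chromosome 1 at 19980299 to 19981199 and AT1G52560 on chromosome 1 at 19574538 to 19575866. HSP23.6-MITO has a copy of 96.8% identity elsewhere and is uncertain in origin. Without ddcc replicate 1 or 2 limma called none of the members, with 12 and 9 lower at an unadjusted p under 0.05, and without wild-type replicate 2 it called 8 and AT1G52560 and HSP101 were not among them (adjusted p = 0.0594 and 0.0739). HSFA9 was not called without wild-type replicate 1 (0.129), after quantile normalisation (0.11) or with equal nuclear totals (0.135).

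LEA transcripts, which accumulate as seeds prepare for drying, were also lower in ddcc. M17 fell from 43423 ± 9223 to 10072 ± 1904 (log2 fold change -2.10, adjusted p = 0.00357), ATECP31 from 2249 ± 80.0 to 949 ± 40.9 and GEA6 (EM6) from 18449 ± 3785 to 6896 ± 131. Of 25 members tested 7 were called lower and none higher, and adjusted over the list alone 12 were lower. The list held 7.36% and 7.59% of reads in ddcc and 10.8% and 10.98% in wild type, with a median log2 fold change of -0.71 (camera adjusted p = 1.09e-07; adjusted p = 0.27 with an estimated correlation and 0.0429 with fry). Quantile normalisation ended the list's call (median -0.07, adjusted p = 0.193) and left 3 members called. With equal nuclear totals 3 members were called, and the list kept its call (adjusted p = 8.18e-07) at a median of -0.32, or -0.69 relative to all genes. Without ddcc replicate 1 or 2 limma called none, with 3 lower at an unadjusted p under 0.05 in each, and without wild-type replicate 1 it called 4.

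Seed storage protein genes showed no called member among 13. PAP85, a vicilin-like protein gene, stood at 27236 ± 4700 in ddcc and 34546 ± 2414 in wild type (adjusted p = 0.643), and the cruciferin gene CRU2 at 2255 ± 235 and 4219 ± 908 (adjusted p = 0.0557). When adjusted over the list alone, 1 member was higher and 1 lower. The list held 7.65% and 8.41% of reads in ddcc and 8.13% and 8.60% in wild type, and its median of -0.25 (camera adjusted p = 0.111) turned positive after quantile normalisation (0.23) and with equal nuclear totals (0.14, or -0.23 relative to all genes), each with 1 member higher, while without wild-type replicate 2 it was -0.54 (adjusted p = 1.93e-04) and CRU2 passed (0.0432). In the oil body and oil synthesis list the oleosin genes OLEO2, OLEO4 and AT3G01570 and the caleosin gene ATPXG2 fell, with log2 fold changes of -1.04, -1.02, -1.11 and -0.98, while FAD2, the oleate desaturase gene, rose from 82.5 ± 4.50 to 202 ± 11.6 (adjusted p = 0.00495). OLEO1, the most abundant member, did not pass (11831 ± 2830 against 19296 ± 6205, adjusted p = 0.281; it overlaps AT4G25150). Of its 13 members 1 was higher and 4 were lower, also adjusted over the list alone, and its median was -0.52 (camera adjusted p = 0.0453; adjusted p = 0.478 with an estimated correlation and 0.271 with fry). The oil list lost its call after quantile normalisation (median -0.09, adjusted p = 0.633), with equal nuclear totals (0.116), in limma without a trend (0.0808), without a filter (0.0785), with a pseudocount of 5 units (0.051) and without ddcc replicate 1 (0.401), ddcc replicate 2 (0.0663) or wild-type replicate 1 (0.111). Under both scalings none of the oleosin and caleosin genes of the list was called, and without either ddcc library no member was. Without wild-type replicate 1, AT3G01570 (0.0514), OLEO2 (0.0969) and ATPXG2 (0.076) were not called.

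Among 24 tested regulators of seed maturation and abscisic acid genes, ABI3, a master regulator of maturation, was the only member called, higher in ddcc at 479 ± 117 against 263 ± 11.5 (adjusted p = 0.0422), while 3 were higher with equal nuclear totals. ABI5, a bZIP factor of the abscisic acid response, was at 1169 ± 105 and 1731 ± 401 (adjusted p = 0.202). No member passed adjusted over the list alone. The list had a median of -0.01, a mean of 0.00105 and a camera test pointing down (adjusted p = 0.782). ABI3 lost its call without any 1 library, with adjusted p = 0.294 and 0.519 without ddcc replicates 1 and 2 and 0.11 and 0.155 without wild-type replicates 1 and 2.

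Of 9 tested genes tied to germination 5 were called higher in ddcc. Besides EXPA2 these were EXPA1 (read ratio 16.6, interval 4.05 to 146), the mannanase gene MAN7 (9.46 ± 1.9 to 52.6 ± 5.78), the cysteine proteinase gene CP1 (33 reads against 1, read ratio 52.0, interval 8.71 to 2117) and RGL2 (13.5 ± 0.397 to 56.1 ± 7.23), a DELLA protein gene that represses germination. The glyoxylate cycle genes, which mobilise oil, were not called. MLS, the most abundant member, stood at 6103 ± 1389 in ddcc and 10749 ± 3886 in wild type (adjusted p = 0.178), and ICL at 5207 ± 429 and 6950 ± 1739. With 6 higher and 1 lower adjusted over the list alone, the median was 1.93 (camera adjusted p = 5.57e-05; adjusted p = 0.27 with an estimated correlation and 0.0234 with fry). The share of reads did not follow these members, since it was 0.863% and 1.0% in ddcc and 1.11% and 1.02% in wild type. Without ddcc replicate 1 or 2 none was called in limma, with 5 higher at an unadjusted p under 0.05 in each, and without either wild-type library 3 were, EXPA1 (adjusted p = 0.0705 and 0.0503) and CP1 (0.0568 and 0.0819) not among them.

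Photosynthesis and chlorophyll genes went both ways. RBCS1A, for the small subunit of Rubisco, rose from 8.07 ± 4.71 to 70.5 ± 1.18 (adjusted p = 5.46e-04), and AT4G11910 (NYE2), a relative of the chlorophyll breakdown gene NYE1, fell from 493 ± 143 to 263 ± 1.35 (adjusted p = 0.0425). NYE1 itself, the most abundant of the 13 members, was at 786 ± 119 and 984 ± 241 (adjusted p = 0.503), and the antenna protein gene LHCB3 at 5.37 ± 2.27 and 16.5 ± 2.51 (adjusted p = 0.0882). There were 1 higher and 2 lower adjusted over the list alone, and the list's median was 0.08 (camera adjusted p = 0.663), which was 0.37 and 0.01 without ddcc replicates 1 and 2 and 0.33 with equal nuclear totals, where 2 were higher and none lower. In the seed coat list of 9 genes, the flavonoid pathway genes F3H (10.1 ± 2.67 to 40.6 ± 0.675) and TT7 (4.43 ± 0.543 to 19.1 ± 6.08) rose, and ARA12, the subtilase gene needed for mucilage release, stood at 475 ± 3.95 and 418 ± 16.6 (adjusted p = 0.675). It had 3 higher members adjusted over the list alone and a median of 0.18 (camera adjusted p = 0.166; 0.0373 with a filter at 5 units), which was -0.01 without wild-type replicate 2. Of 5 cell cycle genes none was called. CYCB1;1 was at 21.5 ± 2.85 and 14.5 ± 4.99 (limma adjusted p = 0.457). MCM3 had 8 reads in ddcc and 0 in wild type, 4.21-fold against the floor of 3 reads (limma adjusted p = 0.0899). The list had 1 higher member adjusted over the list alone and a median of 0.57 (camera adjusted p = 0.13), which was 1.09 without wild-type replicate 1 (0.0483) and 0.23 without wild-type replicate 2. It was also called in limma without a trend (0.0412). F3H overlaps AT3G51238 and is uncertain in origin. It was not called without wild-type replicate 2 (adjusted p = 0.0662), and neither F3H (0.283 and 0.393) nor RBCS1A (0.23 and 0.345) was called without ddcc replicate 1 or 2. TT7 was not called without any 1 library (0.419 and 0.393 without ddcc replicates 1 and 2, 0.106 and 0.141 without wild-type replicates 1 and 2), nor AT4G11910 without ddcc replicate 1 (0.417) or 2 (0.464), without wild-type replicate 1 (0.157), after quantile normalisation (0.114) or with equal nuclear totals (0.2).

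Genes of the chloroplast genome were higher in ddcc, with 33 of 74 tested called higher and none lower. They took 3.46% and 3.63% of reads in the ddcc libraries and 1.76% and 1.55% in wild type. There were 52 higher adjusted over the list alone, and the median log2 fold change was 0.82 (camera adjusted p = 4.34e-25; adjusted p = 0.325 with an estimated correlation and 0.104 with fry). Of 42 genes of the mitochondrial genome 1 was called higher, also adjusted over the list alone, with a median of 0.36 (camera adjusted p = 0.00222; adjusted p = 0.325 with an estimated correlation and 0.129 with fry) and 0.549% and 0.451% of reads in ddcc against 0.32% and 0.339% in wild type. Without ddcc replicate 1 or 2 limma called none of the chloroplast genes, with 40 and 27 higher at an unadjusted p under 0.05, and without wild-type replicates 1 or 2 it called 24 and 6. No mitochondrial gene was called in limma without ddcc replicate 1, ddcc replicate 2 or wild-type replicate 1, with 1, 4 and 5 higher at an unadjusted p under 0.05.

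Markers of other tissues were few. Of the silique wall and flower markers 3 were tested and none was called, also adjusted over the list alone: SHP1, a valve margin gene that overlaps AT3G09155 and AT3G58790, was at 9.53 ± 4.58 in ddcc and 11.3 ± 7.70 in wild type (adjusted p = 0.916), and AP3, a petal and stamen gene, had 4 reads in each genotype (adjusted p = 0.647). Of the endosperm markers 3 were tested and none was called, with 1 higher and 1 lower adjusted over the list alone. EPR1, an extensin-like gene of the endosperm, was at 27943 ± 6038 in ddcc and 14846 ± 1252 in wild type (adjusted p = 0.15) and passed after quantile normalisation (0.00192) and with equal nuclear totals (0.0085). Through EPR1 the endosperm markers held 1.79% and 2.28% of reads in ddcc and 0.771% and 0.924% in wild type. Of the defence list 2 genes were tested and none was called, also adjusted over the list alone: AT1G58602, which has a copy of 98.5% identity and overlaps AT1G58561, had 8 reads against 5, and SNC1, with a copy of 96.2% identity, had 4 against 4. Among 9 reference genes AT5G60390 (an elongation factor gene that overlaps AT5G60400) and GAPC1 were higher in ddcc, with log2 fold changes of 1.06 and 1.36 (adjusted p = 0.0114 and 0.0104), and 3 were higher adjusted over the list alone. The median of that list was -0.12, its mean 0.23 and its camera test pointed up (adjusted p = 0.331). The median was 0.07 after quantile normalisation and -0.11 relative to all genes with equal nuclear totals, and 0.11 without ddcc replicate 2. Neither gene was called without ddcc replicate 1 (0.342 and 0.279), ddcc replicate 2 (0.378 and 0.393) or wild-type replicate 1 (0.0631 and 0.066).

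**Figure D3:**
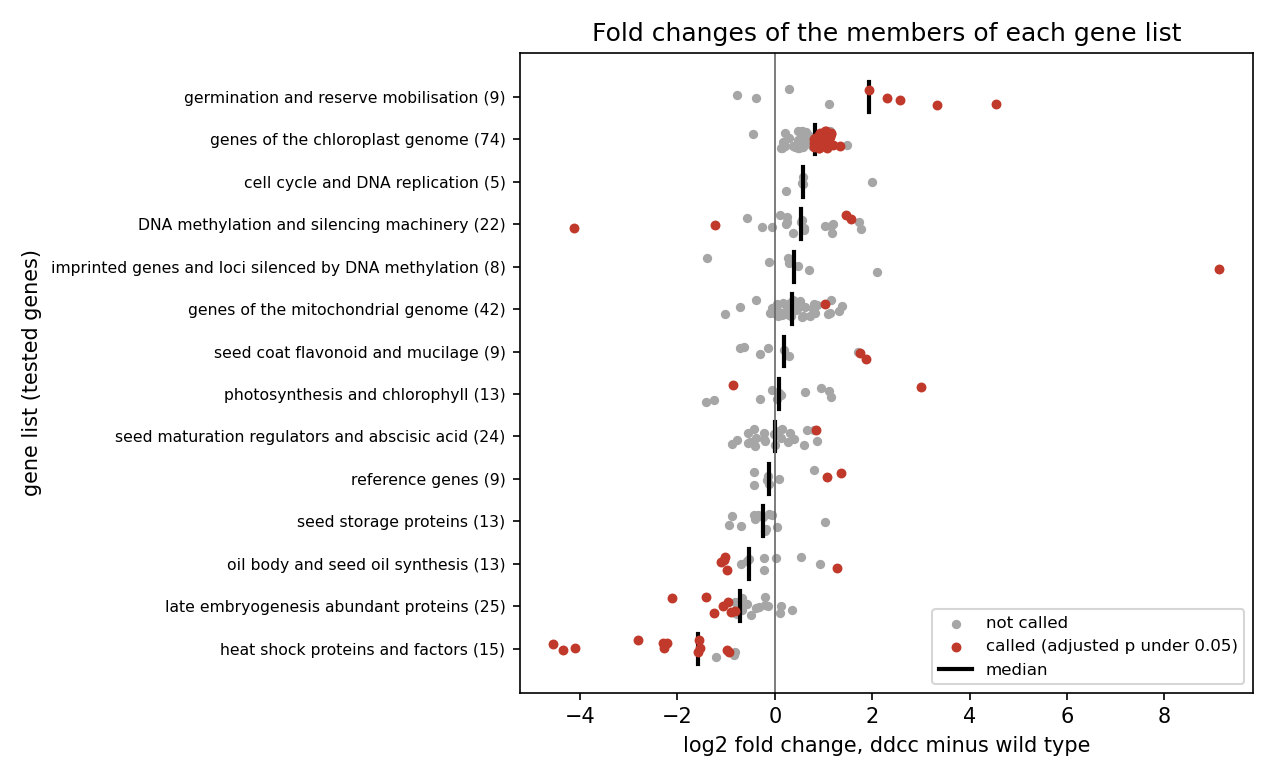
Log2 fold changes of the tested members of each gene list, ddcc over wild type, with 1 point per gene and a bar at the list's median. The medians lie at -1.57 for heat shock genes, -0.71 for LEA genes, 1.93 for germination genes and 0.82 for genes of the chloroplast genome.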

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

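The voom analyses and the thinning of reads were chosen after the data were seen. The planned edgeR and DESeq2 tests were not run, because the deposited values do not lie on even steps, and the planned comparison of transposable element genes was not made. Of the results and settings compared, 813 kept their direction and their side of the threshold or, for counts, stayed within 1.5 times, 128 were weaker, 29 stronger and 20 reversed. The count of 1023 called genes (478 higher, 545 lower) became 336 (191, 145) without a filter, where 19745 genes were tested, 1553 (1349, 204) with equal nuclear totals, 33 (32, 1) in limma without a trend, 309 (174, 135) at an adjusted p under 0.01, 1805 (1585, 220) with voom on library totals and 581 (283, 298) with reads thinned to equal depth; voom with effective library sizes called 1181. With 1 library left out the counts ran from 1 to 455 in all, 1 to 276 higher and 0 to 225 lower, where a lone library is assumed to vary like those of the other genotype. Apart from fewer libraries, more tested genes, fewer reads and the stricter threshold, the cause was not tested. The 7 called gene lists became 4 after quantile normalisation, 3 with equal nuclear totals, which leaves out the 2 organelle lists, and 0 with an estimated correlation. For the LEA, germination and imprinted lists the estimated correlation (-0.00544, -0.102 and -0.138) lay below the preset 0.01. A higher correlation among members therefore did not end the calls of these lists. For the chloroplast genome, heat shock, oil and mitochondrial genome lists it lay above the preset (0.421, 0.352, 0.18 and 0.0434). The camera p-values of those lists at the preset therefore understate the uncertainty. With an estimated correlation camera also takes its degrees of freedom from the 4 libraries instead of the number of genes. These changes were not separated. With fry the imprinted, LEA and germination lists passed (adjusted p = 0.0402, 0.0429 and 0.0234), the other 4 called lists did not, and no uncalled list did. The storage list was called with voom (0.0296), and the imprinted list was not, with voom (0.0616), with voom on library totals (0.203) or with thinned reads (0.0853). QQS passed with voom on library totals (0.0395). In limma without a trend no heat shock, LEA, chloroplast genome or translation gene was called, with 13 and 8 lower and 39 and 121 higher at an unadjusted p under 0.05. DRM2 kept its log2 fold change of -2.36 in limma without a trend but not its call, and ranged from -2.67 to -2.04 with 1 library left out.

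The genes and lists whose direction reversed were uncalled ones, and the median of the glucosyltransferase family turned with equal nuclear totals (0.09) and with voom on library totals (0.07). After quantile normalisation the log2 fold changes of PAP85, NYE1 and MLS were 0.29, 0.056 and 0.12, the storage protein list 0.23 and the maturation list 0.14. With equal nuclear totals PAP85, NYE1, SHP1 and the maturation list were at 0.042, 0.083, 0.20 and 0.36, and with voom on library totals at 0.012, 0.044, 0.055 and 0.40. With a filter at 5 units the camera direction of the maturation list turned at a median of -0.00704. Thinned reads gave a median of -0.17 for the photosynthesis list and log2 fold changes of -0.23 for SNC1 and 0.27 for SHP1. With 1 library left out SNC1 ranged from -0.043 to 0.71, SHP1 from -0.79 to 0.52 and the maturation list from -0.115 to 0.0956. The cause of these was not tested.

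The replicate numbers did not pair the libraries: the differences between replicates 1 and 2 had a correlation of -0.05 between genotypes across genes. With the replicate block 1381 genes were called (670 higher, 711 lower), and the oil list was not called (adjusted p = 0.157), while QQS passed (0.018). Depth differed between libraries: wild-type replicate 1 had 3416071 reads and the other 3 libraries 1122934 to 1292023. Over simulated genes of all levels, 25.8% of 2-fold changes were recovered at the inferred dispersion and 0% at a dispersion of 0.131. Recovery by expression level was not examined, and the simulated genes did not differ in dispersion.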

Other observations

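The enrichment tests, the choice of product names, the tests of the heat shock genes, the test of green tissue and the count of other splits were chosen after the results were seen. Fisher's exact tests treat genes as independent draws. Their p-values leave out variation between libraries and the shared variation of genes of the same process or family.

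Genes annotated to translation were called higher in ddcc more often than the background. Of 353 such genes tested, all of them nuclear, 86 were called higher, where 14.01 would follow from the background (Fisher's exact test, one-sided, adjusted p = 1.16e-44 over 207 process terms), and 5 lower. Examples are the ribosomal protein genes AT1G15930 (65.7 ± 12.8 to 294 ± 6.70) and AT4G16720 (157 ± 62.3 to 654 ± 74.5). Of 10 genes annotated with the Barwin-related endoglucanase domain 4 were higher (Fisher's exact test, adjusted p = 0.044). Among them was the expansin gene EXPA9, 22.6-fold higher against the floor of 3 reads. The xyloglucan-modifying enzyme genes XTH31 and XTH19, chosen after their values were seen, were also called higher, with read ratios of 85.2 (interval 14.7 to 3426) and 82.0 (14.1 to 3301). Of 30 GDSL lipase genes 7 were higher and 1 lower (adjusted p = 0.0133), with AT5G14450 rising from 8.75 ± 2.28 to 82.6 ± 16.2. Without ddcc replicate 1 or 2 none of these genes was called in limma, with 94 and 107 of the translation genes higher at an unadjusted p under 0.05. Of the translation genes 40 and 38 were called higher without wild-type replicates 1 and 2 and 153 with equal nuclear totals, and of the GDSL lipase genes 5 and 3 without wild-type replicates 1 and 2.

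Calls of lower genes were enriched in 3 families named here, although most members did not pass. Of 68 genes with the glucosyltransferase domain, which attaches sugars to hormones and other small molecules, 11 were lower (adjusted p = 0.00182), among them UGT74E2 (543 ± 76.8 to 124 ± 31.1) and UGT74F2 (937 ± 46.6 to 357 ± 11.2). The family's median of -0.30 was 0.09 with equal nuclear totals, or -0.29 relative to all genes. There 3 were called lower and 2 higher, and without wild-type replicate 1 or 2 there were 5 and 8 lower. Of 36 core histone genes 7 were lower (adjusted p = 0.0126), with HTA13 falling from 103 ± 30.2 to 23.3 ± 0.419, and 5 of 11 genes of the glyoxalase domain were lower (adjusted p = 0.00182), among them PDS1 (676 ± 243 to 188 ± 31.5), which acts in tocopherol synthesis. With equal nuclear totals 4 histone and 2 glyoxalase genes were called lower, without wild-type replicate 1 there were 1 and 2, and without wild-type replicate 2 there were 4 and 3. Of 4 tested genes with Ulp1 protease as product, a name picked from the called genes, 3 were higher: AT5G45570 (read ratio 55.2, interval 18.4 to 272), AT5G28810 (24.4, 6.22 to 211) and AT4G08430 (12.1, 3.65 to 62.9). Their best copies elsewhere have 100%, 96.8% and 97.8% identity, so that a rise at these genes and reads from a copy cannot be told apart. AT4G08430 was not called without wild-type replicate 1 or 2 (adjusted p = 0.0528 and 0.131), nor AT5G45570 without replicate 2 (0.0653). Of 15 tested genes whose product names a transposon or transposase 3 were higher, all of them Ta11-like retrotransposon loci. AT2G41590 and AT2G16676 were 17.9-fold and 14.2-fold higher against the floor of 3 reads. AT2G13450 had a read ratio of 33.1 (interval 5.33 to 1370), has a copy of 97.0% identity and is uncertain in the same way. It lost its call without wild-type replicate 2, at a log2 fold change of 2.78. Without ddcc replicate 1 or 2 none of the genes of these families was called in limma, with 17 and 13 glucosyltransferase, 9 and 11 histone and 6 and 5 glyoxalase genes lower and 3 Ulp1 genes higher in each at an unadjusted p under 0.05.

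Genes that were nearly silent in wild type, with 3 reads or fewer, were called higher 62 times, against 11 genes that were nearly silent in ddcc and called lower. Wild type was the deeper genotype, so thinning its reads to the ddcc depth had to raise the ratio of the first kind to the second (21.04 in the median of 20 draws, lowest 13.2), and this decides nothing about depth. A copy of at least 95% identity was found for 24.6% of the 61 searched genes (exact 95% interval 14.5 to 37.3), against 5.2% of 500 uncalled genes, too few for shared reads to explain the whole group. For the 15 genes with a copy, of which 53.3% had one of at least 98% identity, a rise at the gene and reads from its copy cannot be told apart. That loci near repeats lose silencing with the methylation is a hypothesis, found and tested on the same data. A pseudogene lay within 5 kb of 27.9% of these genes and 13.2% of the others (odds ratio 2.55, Fisher's exact p = 0.002, two-sided). Of the 11 genes nearly silent in ddcc and called lower, 1 had such a neighbour. The others were the remaining tested genes, not matched for expression level. The test therefore cannot separate loss of silencing from low expression in wild type. Most calls of the 62 genes were also lost with any 1 library left out.

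The heat shock list had a median of -1.57, which was -1.19 with equal nuclear totals (quartiles -2.16 and -0.77 over its 15 members, 9 of them called lower), so that this scaling moved it but argues against scaling as the whole cause. With any 1 library left out the list median stayed at -1.38 or lower, so that no single library carried it. Seeds of the 2 genotypes may have been harvested at different points of maturation; the storage protein genes had a median of -0.25 with no called member, 7 LEA genes and 4 oil body genes fell, and no sample in the design separates genotype from stage, so that these cannot be told apart. An effect of the mutation on the heat shock programme stays open and untested.

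The rise of the translation genes was not removed by a fit on GC content, exon length and expression level, which left 134% of its median. The bootstrap interval of 110 to 153 resampled genes, not libraries, so it leaves out variation between libraries. The median of 0.55 was 0.55 after quantile normalisation and 0.92 with equal nuclear totals. Green tissue in the ddcc samples may have added reads, since chloroplast genome genes and RBCS1A rose with them; the median of the nuclear photosynthesis genes was 0.079 with members going both ways and ran from 0.01 to 0.37 with 1 library left out, which leaves this open. No biological explanation was tested for this group.

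The 4 libraries allow 3 splits into 2 and 2, too few for a share under 0.05. The real split gave 1023 called genes and the highest other split 0, with 1 of the 3 splits reaching the real count.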
